A study of Nothobranchius furzeri with 20 samples.

How the data were processed

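RNA-seq read counts from the livers of 20 male Nothobranchius furzeri (turquoise killifish) of the short-lived GRZ strain were analysed, with 5 fish each at 5, 7, 10 and 14 weeks of age. Per the labels, total RNA was used and libraries were made with the TruSeq RNA v2 kit, which does not mark strand. Per the submitters' processing notes the tools used upstream were CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4; CASAVA is a base caller, STAR an aligner and featureCounts a read counter. The genome build, the gene annotation and the counting options are not given in the sources used here. Age groups were taken from the age given for each sample. Fish are numbered 1 to 5 within an age only to name them, and no number links fish of different ages. The labels give each library its own number but do not say more about the separateness of the animals, so p-values measure the spread between these samples. Dates, feeding, tanks and sequencing batches are not given in the sources used here.

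The authors deposited a table of raw read counts per gene, as whole numbers, for 26739 gene identifiers. At least 1 read was counted for 22484 of them. Column totals ran from 22529235 to 42886761 counts, and a gene with no count in a library was bounded at 3 counts. On these totals, before the TMM scaling described below, this is between 0.0700 and 0.133 CPM (counts scaled to library size) depending on the library. The CPM of genes given below are TMM-scaled, on which 3 reads were 0.1441 CPM in 10-week fish 2 and 0.05891 CPM in 10-week fish 3. The bounds cover counting error only. All 40 pairs of fish of the same age differed by far more than sampling noise. The smallest chi-square per degree of freedom was 64.84, over genes with a summed count of at least 20. This argues against repeat counts of the same library within an age. Separate libraries of the same animal could also differ by more than sampling noise, so it does not show separate animals. Every library was counted as a separate sample.

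The authors also deposited a table named RPKM (reads scaled by gene length and library total), whose values did not use each library's own total. A value equalled the read count divided by a gene length and by a total, but the total ran from cell to cell through a cycle of 25 numbers. With this cycle the residual SD was 0.000305 on the log2 scale over 13267 genes, against 0.321 with each column's own total and 0.226 with 1 common divisor. Of the 25 totals, 20 matched the 20 count totals in file order and 5 matched none. With the cycle, 100% of the nonzero values of genes reaching 1 RPKM were rebuilt within 0.1% or within 0.0015. The length of each gene was itself taken from its highest value. Single deposited RPKM values therefore departed from the RPKM of their own library by up to 2.05-fold, with an SD of 0.323 on the log2 scale. The deposited RPKM were used only in an alternative test. The gene lengths implied by this table were used for checks of gene length. The search for the cycle was tested on a simulated table of 5012 genes, in which the cycle of 25 was found.

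The identifiers have no gene names in the files. None of them matched any of 38438 genes of the reference table for assembly NfurGRZ-RIMD1 by identifier, locus tag, synonym or accession (0 matches), so no gene is named or placed on a chromosome here. Lists of pathway and cell type genes, fixed before the data were examined, could not be applied, and the tests planned on them were not run. Reads shared between near-identical gene copies, and reads from overlapping or antisense genes, could not be separated in these counts.

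Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the age groups, which left 16475 genes, and library sizes were scaled by TMM. A model with 1 mean per age was fitted to all 20 libraries, so that all ages shared the estimate of spread, and quasi-likelihood F-tests were made of any difference among the 4 ages and of pairs of ages. A slope per week of age was tested in a separate model. P-values were adjusted by Benjamini-Hochberg within each test, and a gene was called at an adjusted p under 0.05 with no fold threshold. Standard errors are the log2 fold change divided by the square root of its F statistic. Comparisons of 14 with 5, 7 with 5, 10 with 7 and 14 with 10 weeks, the test over all ages and the slope were planned before the data were examined. Comparisons of 10 with 5 weeks, 14 with 7 weeks, and 7 weeks with the mean of the other ages were added after seeing the data. Log2 CPM used a prior count of 2.

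Individual genes were chosen by a rule fixed beforehand. For each of the 4 planned comparisons of ages, called genes needed a mean of at least 5 CPM in the higher group and no overlap between the fish of the 2 ages. Because no symbols were available, up to 2 identifiers with the largest rise and 2 with the largest fall were taken per comparison, and the 2 with the smallest adjusted p in each direction for the slope. The rule gave 17 genes; 1 further gene is named outside it.

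The planned tests of genes, but not the 3 added comparisons, were run on simulated counts with 100 genes changed by log2 1 and 100 by log2 2. The shares called are of the changed genes that passed the count filter, which dropped a few of them in some tests. For 14 versus 5 weeks, 14.3% and 74.5% were called among 16284 genes with 2 false calls. For 7 versus 5 weeks the shares were 20.6% and 68% among 16324 genes with 3 false calls. For 10 versus 7 weeks they were 21% and 83% among 16300 genes with 6 false calls, and for 14 versus 10 weeks 28% and 72% among 16293 genes with 9 false calls. The slope recovered 34.3% and 78% with 5 false calls, and the test over all ages 13.5% and 71.4% with 4 false calls.

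Alternatives were DESeq2 1.42.0 size factors in edgeR, total counts alone, no low-count filter, a mean count of at least 50, DESeq2 as the test, limma-voom (limma 3.58.1), limma on log2 deposited RPKM with pseudocounts of 0.1 and 1 and a mean RPKM of at least 0.5, the 20 most abundant genes left out, only the 10 libraries of the ages compared, log2 of age, and each fish left out in turn. Alternatives added after seeing the data were RPKM rebuilt with each library's own total, removal of per-library trends on gene length, thinning of every library to the smallest total, and omission of 5-week fish 1 and 2 or of 14-week fish 5. The spread between fish was the SD of log2 CPM over the 5 fish of an age, as the median over tested genes, with ages compared by 100 permutations of group-centred values. Other splits of the fish were counted with 100 splits per test. Tables were also handled in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.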

Results

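Liver transcriptomes were measured by RNA-seq in male killifish of the GRZ strain, an inbred line with a short life span, at 5, 7, 10 and 14 weeks of age (n = 5 fish per age). The question posed by the series was how liver gene expression differs between age groups. Total counts per library ran from 22529235 to 32050062 at 5 weeks, 24566917 to 37122038 at 7 weeks, 24330529 to 42886761 at 10 weeks and 24890288 to 34710218 at 14 weeks. Between 19032 and 20524 genes had at least 1 read in a library. The 20 most abundant genes took 20.63% to 34.2% of the counts of a library. All genes are given by the identifiers of the deposited table, which the sources used here do not pair with names, functions or positions.

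Livers at 7 weeks stood apart from those of 10 and 14 weeks on the first principal component, and from all other ages in the number of genes that differed. On the first principal component of log2 CPM, which held 26.5% of the variance, the 7-week fish lay between -91.2 and -36.9. The 10-week fish lay between 25.31 and 51.82 and the 14-week fish between 12.9 and 65.6. The 5-week fish spanned -60.1 to 21.4, and 5-week fish 1 and 2, at -57.6 and -60.1, lay among the 7-week fish on this component. The second component, with 16.7% of the variance, placed these 2 fish at 84.1 and 69.0, away from the 7-week fish, of which the highest lay at -4.06. On this component 5-week fish 4, at 72.3, lay with 5-week fish 1 and 2. The median Spearman correlation between fish of the same age was 0.901 at 5 weeks, 0.961 at 7 weeks, 0.959 at 10 weeks and 0.958 at 14 weeks (10 pairs each, across genes, which are not independent replicates). Between 10- and 14-week fish it was 0.945, above the 0.903 between 7- and 10-week fish and the 0.895 between 7- and 14-week fish. It was as low between 5-week fish and those of 7 weeks (0.910), 10 weeks (0.901) and 14 weeks (0.902), so this measure did not single out 7 weeks.

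**Figure D1:**
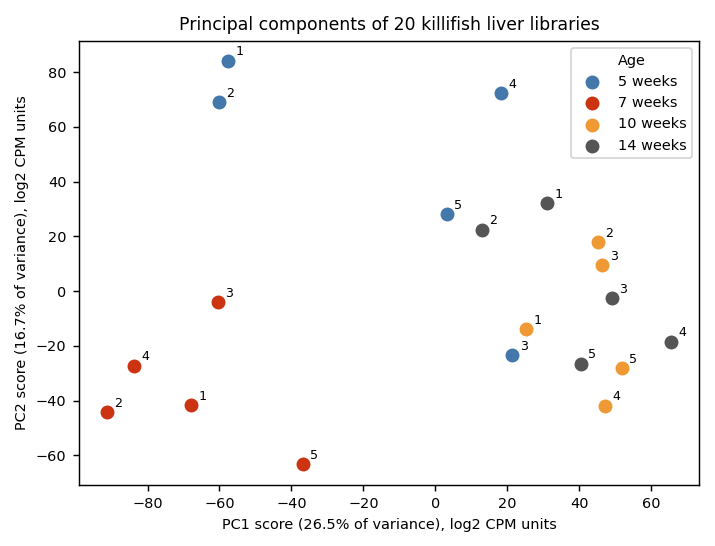
Scores of the 20 liver libraries on principal components 1 and 2 of log2 CPM, with 1 point per fish, coloured by age and numbered within age. The 7-week fish lie at -36.9 or below on component 1, all 10- and 14-week fish lie at 12.9 or above, and the 5-week fish are spread over -60.1 to 21.4.

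Over all 4 ages, 5893 of 16475 tested genes (35.8%) differed in the omnibus test. The 7-week mean was the farthest from the mean of the other ages in 4031 of these genes (68.4%), with 2361 higher and 1670 lower at 7 weeks. The 5-week mean was the farthest in 1042 genes, the 10-week mean in 467 and the 14-week mean in 353. Among all tested genes, called or not, 7 weeks was the farthest age in 50.6%. In a comparison added after seeing the data, 5686 genes differed between 7 weeks and the mean of the other ages, 3140 higher and 2546 lower at 7 weeks. The deposited RPKM gave 2102 genes in the omnibus test with a pseudocount of 0.1 and 2925 genes for 7 weeks against the other ages.

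**Figure D2:**
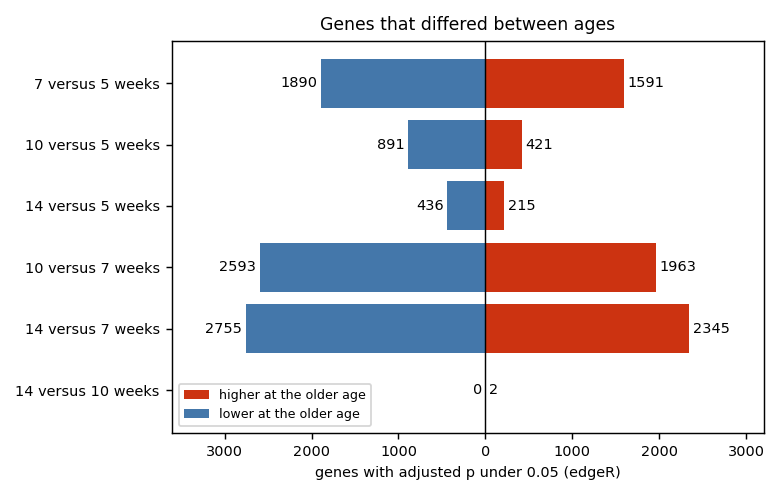
Number of genes with an edgeR adjusted p under 0.05 for each pair of ages, with genes higher at the older age drawn to the right and genes lower at the older age to the left. Each comparison that includes 7 weeks gives at least 3481 genes, while 14 against 10 weeks gives 2.

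The comparison of 7 with 5 weeks asks which genes changed first. Of the tested genes, 1591 rose and 1890 fell from 5 to 7 weeks (3481 in all, 21.1%). The change was at least 2-fold in 2094 of them, and the median absolute log2 change was 1.13. None of the 20 most abundant genes was called (0 higher, 0 lower). Among called genes whose fish did not overlap and whose mean reached 5 CPM in the higher group, the largest rises were those of Nfu_g_1_018107 and Nfu_g_1_017949. Nfu_g_1_018107 rose from 1.13 ± 0.838 to 35.1 ± 28.8 CPM (SD, n = 5; log2 fold change 4.95, SE 0.758, adjusted p = 0.00055). Nfu_g_1_017949, of 7545 bp, rose from 72.1 ± 68.6 to 2090 ± 577 CPM (SD, n = 5; log2 fold change 4.86, SE 0.768, adjusted p = 0.000669). Both stood lower again at later ages, with Nfu_g_1_018107 at 0.214 ± 0.149 and 0.223 ± 0.143 CPM and Nfu_g_1_017949 at 138 ± 120 and 93.3 ± 52.5 CPM at 10 and 14 weeks (SD, n = 5). The largest falls were those of Nfu_g_1_017500 and Nfu_g_1_016656, and 5-week fish 1 decided the size of both. Nfu_g_1_017500 went from 29.3 ± 63.1 to 0.311 ± 0.227 CPM (SD, n = 5; log2 fold change -6.52, SE 1.38, adjusted p = 0.00463). Its log2 fold change was -1.74 without 5-week fish 1, in which it reached 142.1 CPM. Nfu_g_1_016656 went from 11.1 ± 17.6 to 0.494 ± 0.472 CPM (SD, n = 5; log2 fold change -4.50, SE 1.05, adjusted p = 0.00769), and the log2 fold change was -2.72 without that fish. Nfu_g_1_016656 was at 29.5 ± 29.1 CPM at 14 weeks (SD, n = 5). Over all alternatives, adjusted p ran from 0.00235 to 0.151 for Nfu_g_1_017500 and from 9.02e-05 to 0.166 for Nfu_g_1_016656. Only 1996 genes were called with the 10 libraries of these ages alone, 733 with the deposited RPKM, 2157 without 5-week fish 4 and 2209 without 7-week fish 2. The split between rises and falls depended on the method and the libraries, with 1796 rises and 1253 falls in limma-voom, 1099 rises and 897 falls with the 10 libraries of these ages and 510 rises and 223 falls with the deposited RPKM.

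From 7 to 10 weeks, 1963 genes rose and 2593 fell (4556 in all, 27.7%), and the change was at least 2-fold in 2748. Of the 20 most abundant genes, 2 rose and 2 fell. Nfu_g_1_000302 rose from 1.18 ± 0.552 to 210 ± 200 CPM (SD, n = 5; log2 fold change 7.48, SE 1.79, adjusted p = 0.00418). Nfu_g_1_002545 rose from 13 ± 14.9 to 1150 ± 753 CPM (SD, n = 5; log2 fold change 6.46, SE 1.54, adjusted p = 0.00409). At 14 weeks their values were uneven: 14-week fish 5 had 784.9 CPM of Nfu_g_1_000302 and the next fish 9.79 CPM, and it had 2085 CPM of Nfu_g_1_002545 against 484.9 CPM in the next fish. Nfu_g_1_007386 fell from 877 ± 601 to 3.08 ± 1.95 CPM (SD, n = 5; log2 fold change -8.15, SE 1.39, adjusted p = 0.000354) and stayed at 3.46 ± 1.64 CPM at 14 weeks. Nfu_g_1_007425 went from 13.9 ± 29.8 to 0.0397 ± 0.0417 CPM (SD, n = 5; log2 fold change -8.55, SE 2.63, adjusted p = 0.0196), and the 10-week value rests on at most 2 reads per fish. At 5 weeks Nfu_g_1_007425 was at 325 ± 446 CPM (SD, n = 5), with fish 4 and 5 at 861.6 and 762.4 CPM. The call of Nfu_g_1_007425 was lost without 7-week fish 3 (log2 fold change -3.93, adjusted p = 0.235) and without 10-week fish 3 (adjusted p = 0.0505), and its adjusted p ran from 0.000792 to 0.507 over all alternatives. The deposited RPKM gave 2184 genes for 10 against 7 weeks with a pseudocount of 0.1, without the excess of falls (1111 rises, 1073 falls). With a pseudocount of 1 they gave 1013 rises and 1112 falls. RPKM rebuilt with each library's own total gave 1749 rises and 2483 falls, and limma-voom gave 1992 and 2701.

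Genes that rose from 5 to 7 weeks often fell again by 10 weeks. Of the 1591 that rose, 1148 (72.2%) fell from 7 to 10 weeks and 6 rose further. Of the 1890 that fell, 848 (44.9%) rose from 7 to 10 weeks and 3 fell further. These comparisons share the 7-week libraries, which by itself sets the changes against each other. Across genes, which are not independent replicates, the changes had r = -0.51, and simulated groups without any effect gave r = -0.50. The covariance was -0.457 against -0.101 in the simulation, a difference of -0.356. The simulation drew genes independently and gave each gene the same spread at all ages. With the 7-week fish divided between the comparisons, r was -0.40 and -0.30 in the 2 arrangements, with 700 and 380 genes called in opposite directions, against 100 and 73.2 for independent lists of the sizes called in each arrangement.

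The comparison of 14 with 5 weeks sets the oldest fish against the youngest. In the fit of all ages 215 genes rose and 436 fell (651 in all, 3.95%), and the change was at least 2-fold in 487. Nfu_g_1_003038 rose from 0.856 ± 0.541 to 37.8 ± 28.9 CPM (SD, n = 5; log2 fold change 5.45, SE 0.934, adjusted p = 0.00531) and was already at 76.8 ± 56.1 CPM at 10 weeks. Nfu_g_1_008170 rose from 0.215 ± 0.189 to 9.04 ± 10.8 CPM (SD, n = 5; log2 fold change 5.32, SE 1.42, adjusted p = 0.0427). Nfu_g_1_021642 fell from 40.8 ± 35.1 to 0.666 ± 1.04 CPM (SD, n = 5; log2 fold change -5.88, SE 1.35, adjusted p = 0.0228). Nfu_g_1_003310 fell from 185 ± 158 to 9.67 ± 15.6 CPM (SD, n = 5; log2 fold change -4.25, SE 0.975, adjusted p = 0.0224). The call of Nfu_g_1_008170 was lost when any of 9 fish was left out, namely 5-week fish 1, 2, 4 and 5, 10-week fish 4 and 5, and 14-week fish 3, 4 and 5, with a highest adjusted p of 0.0849. The calls of Nfu_g_1_021642 and Nfu_g_1_003310 were each lost without 14-week fish 1, 3 or 4, with highest adjusted p of 0.0713 and 0.063. All 3 also missed the threshold with the 10 libraries of these ages alone, at adjusted p of 0.058, 0.05 and 0.139 in that order. Single fish also moved the size of these changes. The log2 fold change of Nfu_g_1_003310 was -6.07 without 14-week fish 2 and -3.61 without 5-week fish 1. That of Nfu_g_1_021642 was -7.52 without 14-week fish 2 and -5.20 without 5-week fish 3. That of Nfu_g_1_008170 was 4.26 without 14-week fish 5 and 5.86 without 5-week fish 2. Over all alternatives, adjusted p ran from 0.000864 to 0.174 for Nfu_g_1_008170, 0.000148 to 0.0713 for Nfu_g_1_021642, 0.000223 to 0.139 for Nfu_g_1_003310 and 2.57e-07 to 0.0438 for Nfu_g_1_003038.

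The number of genes between 14 and 5 weeks depended strongly on the libraries and the test. Only 5 genes were called with the 10 libraries of these ages alone, 1473 with DESeq2, 283 with limma-voom, 79 with the deposited RPKM and 402 without 5-week fish 1 and 2. It was 342 without 5-week fish 2, 1377 without 5-week fish 3, and 339, 184 and 137 without 14-week fish 1, 3 and 4. The excess of falls over rises was not found with every method: limma-voom gave 131 rises and 152 falls, and the deposited RPKM 56 rises and 23 falls. The fit of all ages shared the estimate of spread, although the median SD of log2 CPM was 0.544 at 5 weeks and 0.344 to 0.444 at the other ages. Adjusted p of comparisons with 5 weeks may therefore be too low in that fit, which was not tested.

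Between 10 and 14 weeks 2 genes were called, both higher at 14 weeks, and 1057 genes had an unadjusted p under 0.05. Without any difference, a share of 0.05 of the 16475 tested genes is expected there, which would be most of these 1057. Nfu_g_1_013095, of 303 bp, rose from 14.95 ± 9.05 to 161 ± 103 CPM (SD, n = 5; log2 fold change 3.43, SE 0.547, adjusted p = 0.0337), after 87.8 ± 53.8 CPM at 5 weeks and 34.5 ± 15.2 CPM at 7 weeks. Nfu_g_1_003558, named after its values were seen because it lay below the 5 CPM minimum, rose from 0.0515 ± 0.0463 to 2.47 ± 1.24 CPM (SD, n = 5; log2 fold change 5.59, adjusted p = 0.0143). Its 10-week value rests on at most 3 reads per fish. It lies below the bound for a gene without reads, which is 0.0700 to 0.133 CPM before TMM scaling. The size of the change is therefore uncertain. DESeq2 called 45 genes, 34 higher and 11 lower, and edgeR called 26 without 14-week fish 5. The call of Nfu_g_1_013095 was lost when any of 10 fish was left out, namely 5-week fish 4, 7-week fish 2 and 3, 10-week fish 2, 3, 4 and 5, and 14-week fish 2, 3 and 4, at adjusted p up to 0.219, and over all alternatives it ran from 2.14e-08 to 0.219. No gene was called without 10-week fish 2, 3 or 4 or without 14-week fish 4 (0 genes each), and 1 gene was called without 5-week fish 4, 7-week fish 2 or 3, 10-week fish 1, or 14-week fish 2 or 3.

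Of the genes called between 5 and 7 weeks, 1 was also called between 10 and 14 weeks. This was Nfu_g_1_003558, which fell from 0.545 ± 0.514 to 0.0587 ± 0.0459 CPM between 5 and 7 weeks (SD, n = 5; adjusted p = 0.00872), again with at most 3 reads per fish at 7 weeks, and rose after 10 weeks. Independent lists would share 0.229 genes that fell and then rose and 0.193 that rose in both, and these comparisons have no library in common. The count was 29 with DESeq2 and 16 without 14-week fish 5; it was 0 without 10-week fish 1, 2, 3 or 4 or 14-week fish 4, and 2 without 5-week fish 3 or 10-week fish 5.

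The remaining pairs of ages were compared after seeing the data. From 5 to 10 weeks 421 genes rose and 891 fell, and from 7 to 14 weeks 2345 rose and 2755 fell (2402 in all with the deposited RPKM). Of the 1312 genes called between 5 and 10 weeks, 143 of those that rose and 308 of those that fell were called in the same direction between 5 and 14 weeks, and none in the opposite direction (0 each way). Both comparisons share the 5-week libraries: r across genes was 0.81 against 0.50 in simulations without effect, and the covariance was 0.634 against 0.1. The simulations drew genes independently and gave each gene the same spread at all ages. The 5-week fish had the largest median SD of log2 CPM (0.544, against 0.344 to 0.444 at the other ages). The simulated covariance may therefore be too low here. With the 5-week fish divided between them, r was 0.24 and 0.28, and 71 and 67 genes were called in the same direction, against 27.7 and 22.6 for independent lists of the sizes called in each arrangement. The count from 5 to 10 weeks was 2205 with DESeq2, 621 with limma-voom (345 rises, 276 falls), 285 with the deposited RPKM (228 rises, 57 falls), 241 with the 10 libraries of these ages and 542 without 5-week fish 1 and 2. It was 794, 590 and 2397 without 5-week fish 1, 2 and 3, and 721, 637, 267 and 651 without 10-week fish 1, 3, 4 and 5.

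A linear trend over age was found in 1390 genes, of which 424 rose and 966 fell with age. The means of only 279 of these (20.1%) were ordered by age over all 4 ages, against 6.45% of all tested genes. Nfu_g_1_008889 rose through 0.885 ± 0.755, 2.28 ± 1.15, 11.3 ± 3.30 and 33.4 ± 25.1 CPM at 5, 7, 10 and 14 weeks (SD, n = 5; slope 0.59 log2 units per week, SE 0.0637, adjusted p = 3.07e-05). Nfu_g_1_009323 rose through 0.884 ± 0.901, 1.33 ± 0.771, 5.93 ± 1.09 and 16.6 ± 12.7 CPM (SD, n = 5; slope 0.49, SE 0.0645, adjusted p = 0.000454). Nfu_g_1_026130 fell through 4.76 ± 2.41, 0.742 ± 0.22, 0.3 ± 0.138 and 0.0264 ± 0.0268 CPM (SD, n = 5; slope -0.78, SE 0.0676, adjusted p = 1.75e-06), and its 14-week value rests on at most 2 reads per fish. Nfu_g_1_022937 fell through 2.67 ± 1.82, 1.54 ± 0.616, 0.166 ± 0.132 and 0.0058 ± 0.0130 CPM (SD, n = 5; slope -0.87, SE 0.0874, adjusted p = 1.17e-05), and its 14-week value rests on 1 read in 14-week fish 5. All 4 genes passed the threshold in every alternative run for them. The number of genes with a trend was 2510 with DESeq2, 676 with limma-voom (331 rises, 345 falls), 121 with the deposited RPKM (87 rises, 34 falls) and 839 without 5-week fish 1 and 2. It was 624 and 2457 without 5-week fish 2 and 3, 799, 795 and 796 without 7-week fish 1, 3 and 4, and 786, 447 and 377 without 14-week fish 1, 3 and 4.

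**Figure D3:**
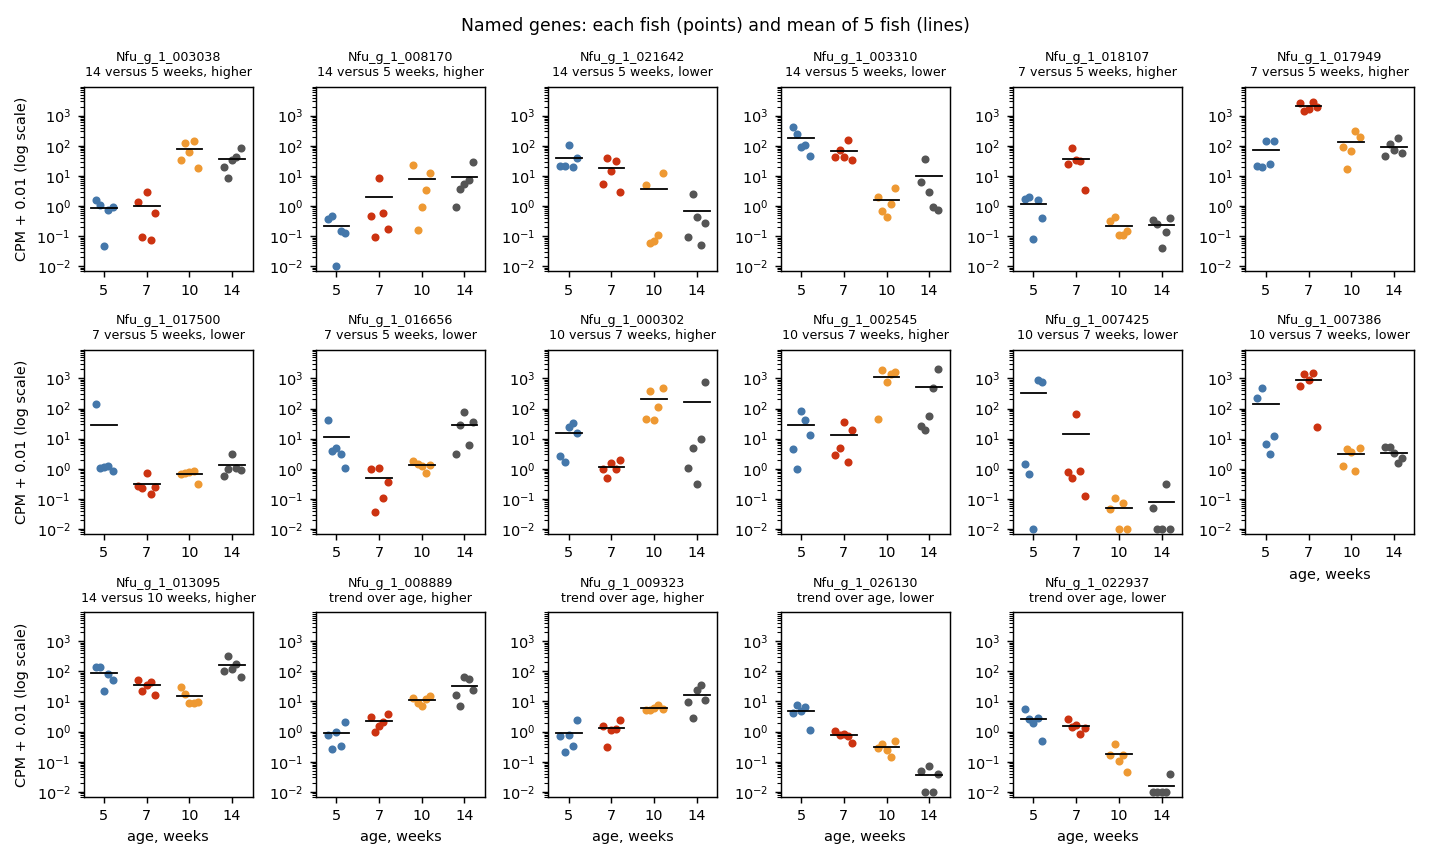
Expression of the 17 genes named by the fixed rule, with 1 panel per gene, age in weeks on the horizontal axis and CPM plus 0.01 on a logarithmic vertical axis. Points are single fish and lines are means of 5 fish; Nfu_g_1_017949 stands at a mean of 2090 CPM at 7 weeks, and Nfu_g_1_017500 owes its 5-week mean to 1 fish at 142.1 CPM.

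The spread between fish was greatest at 5 weeks in the counts of all fish, without passing the test. The median SD of log2 CPM was 0.544 at 5 weeks, 0.344 at 7 weeks, 0.399 at 10 weeks and 0.444 at 14 weeks. The range of these values, 0.200, had a permutation p of 0.119 (100 permutations). The permutation p was 0.0198 without 14-week fish 5, and 0.0396, 0.0495 and 0.0297 without 7-week fish 2, 3 and 5; it was 0.851 without 5-week fish 1 and 2, with a range of 0.1. The order of the ages also depended on the setting. Without 14-week fish 5 the median SD at 14 weeks was 0.309, below the 0.344 at 7 weeks. Without 5-week fish 1 and 2 the median SD was 0.439 at 5 weeks and 0.444 at 14 weeks, and with the deposited RPKM it was greatest at 10 weeks (0.463 against 0.441 at 5 weeks, permutation p = 0.614).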

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

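Tests chosen only after the result was seen were those on the title numbers, on a wrongly labelled sample and on depth among the 5-week fish, and the removal of length trends and thinning applied to the added comparison of 7 weeks with the other ages, together with the splits of the 3 added comparisons; the other tests here were set down before their results were seen. Values of single fish were compared within each age for library measures and named genes, in 96 groups of 5. Chance would single out about 4.8 of these if the values were normally distributed. In 17 groups the highest value lay apart from the rest. CPM values are skewed and the named genes were chosen for large or clear changes, so these numbers cannot be compared directly.

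Gene Nfu_g_1_017500 was at 142.1 CPM in 5-week fish 1 with the next fish at 1.19 CPM, and it also stood out in 7-week fish 3 at 0.709 CPM and in 14-week fish 3 at 3.0 CPM. Nfu_g_1_016656 was at 42.4 CPM in 5-week fish 1, with the next fish at 5.00 CPM. Nfu_g_1_007425 was at 67.15 CPM in 7-week fish 3, with the next fish at 0.822 CPM, and at 0.299 CPM in 14-week fish 4. The comparison did not flag this gene at 5 weeks, where fish 4 and 5 had 861.6 and 762.4 CPM and the other fish 1.41 CPM or less. Nfu_g_1_000302 and Nfu_g_1_002545 were at 784.9 and 2085 CPM in 14-week fish 5. Nfu_g_1_008170 was at 27.84 CPM in 14-week fish 5 and at 8.69 CPM in 7-week fish 3. Nfu_g_1_021642 was at 102.3 CPM in 5-week fish 3 and 2.51 CPM in 14-week fish 2, in which Nfu_g_1_003310 was at 37.33 CPM and the most abundant gene took 6.09% of counts, against at most 4.75% in the other 14-week fish. Nfu_g_1_009323 was at 2.44 CPM in 5-week fish 5 and 7.79 CPM in 10-week fish 4, and Nfu_g_1_022937 was at 0.029 CPM, from 1 read, in 14-week fish 5.

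The 7-week livers differed from the mean of the other ages in 5686 genes. Of these genes 96.8% were still called in the same direction with length trends removed, which argues against gene length bias, and 94.9% were still called after thinning, which argues against library depth. The title numbers of 7-week fish 4 and 5 (64 and 65) lie between those of the 10-week fish (57 to 62) and the 14-week fish (67 to 73), yet on 3922 genes chosen without them these fish showed 106% and 69.4% of the shift of 7-week fish 1 to 3, against processing in title order. With each fish scored on genes chosen without it, the lowest of the 7-week fish showed 70.5% of the 7-week shift and the highest of the 10- and 14-week fish 23.7%, which argues against a fish of 10 or 14 weeks under a 7-week label. No single wrong label made the pattern, since without any 1 fish at least 4412 genes were called. Whether 1 of the 7-week fish was a 5-week fish stays open, since 5-week fish 2 reached 68.9% on the same scale. On the first 2 principal components each 5-week fish lay away from the 7-week fish, with fish 1, 2, 4 and 5 at 28.03 or above on the second against at most -4.06 at 7 weeks and fish 3 at 21.4 on the first against at most -36.9, but the 5-week fish also lay far from each other. Across all tested genes the lowest median Spearman correlation of a 7-week fish with the other 7-week fish was 0.9388, above the highest of a 5-week fish with them, 0.9219, but by less than the SD of the 5-week values, 0.0252. This correlation does not decide for the later ages either, with 10-week fish 1 at 0.9259. A biological difference that goes with age stays open as untested, as do feeding, time of day, tank or an unrecorded batch, which the design cannot separate from age, and a changed mixture of cell types, which cannot be examined without gene names.

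The 5-week fish differed among themselves, with fish 1 and 2 apart from fish 3 to 5 on the first principal component. On the second, fish 4 (72.34) lay with fish 1 and 2 (84.12 and 69), away from fish 5 (28.03) and fish 3 (-23.51). Gene length bias would place fish 1 and 2 outside the other libraries, but the length slopes of both (2 of 2) lay inside the range of the other 18 fish. The lowest slope of that range was that of 5-week fish 3 (-0.0837), so the check does not cover a length bias of that fish. Fish 1 and 2, at 0.0329 and -0.012, also lay between 5-week fish 3 and fish 5 (0.0447). Depth did not account for the separation of fish 1 and 2 either. After thinning to equal totals the median Spearman correlation of these 2 fish with fish 3 to 5 was 0.880. This was below the 0.955 that was the lowest median within another age. No biological explanation was tested, because the labels give all 5 fish the same age, sex and strain.

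Other splits of the fish, 100 per test with the real one included, bear on chance. For all 4 ages 1 split, the real one, gave as many as 5893 genes (highest other 1387), so none of the other splits drawn reached the real count. The same held for 7 versus 5 weeks (1 split, 3481 genes, highest other 1370) and 10 versus 7 weeks (1, 4556, highest other 627). It also held for 14 versus 7 weeks (1, 5100, highest other 2048) and 7 weeks against the other ages (1, 5686, highest other 215). For the trend it held as well (1, 1390, highest other 343). The comparisons of 14 with 7 weeks and of 7 weeks with the other ages were chosen after seeing these data. The splits did not repeat that choice, so for these comparisons they do not exclude chance. For 14 versus 5 weeks 4 splits gave at least 651 genes and the highest other gave 1663. For 10 versus 5 weeks 2 splits gave at least 1312 and the highest other 1590, and for 14 versus 10 weeks 2 splits gave at least 2 and the highest other 11. These shares are also under 0.05, but splits that call more genes than the ages do point to a structure among the fish. There were 4 other splits of the 14- and 5-week or 10- and 5-week fish that reached these counts. Of these, 3 were the ages with 1 fish of each exchanged, and 1 had 2 of each exchanged, so most nearly repeat the ages. The splits with 990 and 1590 genes put 5-week fish 3 with the older fish, and that with 1663 put 5-week fish 5 there. In all of them 5-week fish 1 and 2 were on the same side. Without 5-week fish 3 the real ages gave 1377 genes for 14 versus 5 weeks and 2397 for 10 versus 5. Which structure among the fish this reflects was not tested.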

How the results depend on the processing

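The alternatives added after seeing the data were rebuilt RPKM, removal of length trends, thinning, and omission of 5-week fish 1 and 2 or of 14-week fish 5. Of 363 values of the summary results under other settings, 277 stayed within 1.5 times the count or on the same side of the threshold. None of the genes named by the fixed rule changed direction in 591 refits, and 52 of these missed the threshold. Nfu_g_1_003558 was not among them. The genes were chosen for large or clear changes in the same fish, so their kept direction was largely set by the choice. Planned tests of gene lists were not run, for want of gene names. No paired analysis was possible because the labels give no replicate numbers shared between ages.

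With deposited RPKM (pseudocount 0.1, then 1) counts fell to 2102 and 1994 over all ages, 79 and 71 for 14 versus 5 weeks, 733 and 699 for 7 versus 5, 2184 and 2125 for 10 versus 7, 285 and 253 for 10 versus 5, 2402 and 2329 for 14 versus 7, 2925 and 2835 for 7 weeks against the others, and 121 and 105 for the trend. These values carry the divisors of other libraries, and the median log2 change of all genes moved from -0.0851 to 0.117 for 7 versus 5 weeks and from -0.0722 to 0.137 for 10 versus 5. Rebuilt RPKM gave 263 for 14 versus 5 (130 rises, 133 falls) and 589 for 10 versus 5 (363 rises, 226 falls). For the trend it gave 581 (284 rises, 297 falls), and for 7 versus 5 weeks 1493 rises and 1039 falls. Its counts of 4579 over all ages, 4232 for 10 versus 7 and 4527 for 14 versus 7 stayed within 1.5 times the main counts.

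DESeq2 gave 1473 (14 versus 5), 45 (14 versus 10), 2205 (10 versus 5), 2510 (trend) and 29 (called in both 7 versus 5 and 14 versus 10). Limma-voom gave 283 (14 versus 5), 621 (10 versus 5) and 676 (trend). The cause was not tested for these. The 10 libraries of the ages compared gave fewer genes in 4 comparisons, 5 (14 versus 5), 1996 (7 versus 5), 1 (14 versus 10) and 241 (10 versus 5), and more in the others, 5496 (10 versus 7) and 5303 (14 versus 7). For 14 versus 10 weeks total counts alone gave 1 gene. A mean count of at least 50 gave 0 in edgeR, against 45 called by DESeq2. Of the 1057 genes at an unadjusted p under 0.05 in the main test, most would be expected without any difference.

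Without 5-week fish 1 and 2 the counts were 402 (14 versus 5), 542 (10 versus 5), 839 (trend), 4 (14 versus 10) and 2 (in both intervals). Without 14-week fish 5 they were 26 (14 versus 10) and 16 (in both intervals), and the range of spread was 0.236 (permutation p = 0.0198).

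Leaving out each fish in turn gave 137 to 1377 genes for 14 versus 5 weeks and 2157 to 4230 for 7 versus 5. It gave 0 to 26 for 14 versus 10, 267 to 2397 for 10 versus 5 and 377 to 2457 for the trend. In both intervals 0 to 16 genes were called, and the range of spread ran from 0.169 to 0.236. The 4230 genes were called without 14-week fish 5, and the range of 0.169 was found without 5-week fish 3. The other fish concerned are named with each result. For 10 versus 7 weeks (3602 to 5057), 14 versus 7 (4090 to 5684), 7 weeks against the others (4412 to 6293) and all ages (4667 to 7061) no fish moved the count by over 1.5 times. Depth limits genes near 0.133 CPM before TMM scaling, where 3 reads are expected in the smallest library.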

Other observations

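The position of each fish on the 7-week change, and the relation of gene length to age, are given here; the first, and the omission of 5-week fish 1 and 2 and of all pairs of 14-week fish from the second, were chosen only after the results were seen.

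On 6382 genes called between 7 weeks and the mean of 10 and 14 weeks in a fit without any 5-week fish, 5-week fish 2 showed 68.9% and 5-week fish 1 61.5% of the median 7-week shift. The other 5-week fish showed 23.1% (fish 5), 15.6% (fish 3) and 1.78% (fish 4). With each fish scored on genes called without it, the 7-week fish ranged from 70.5% to 115%, the 10-week fish from -2.44% to 17.26% and the 14-week fish from -16.9% to 23.7%. The 5-week mean was 34.2% with an SD of 29.5 (n = 5). No explanation of these values was tested.

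The lengths of called genes were compared between directions. Genes that fell from 5 to 14 weeks had a median length of 2384 bp and those that rose 3402 bp, against 2806 bp in all tested genes. Genes that fell from 7 to 10 weeks had a median of 2608 bp and those that rose 3045 bp. The order was the same for 10 versus 5 weeks (2771 bp fell, 3343 bp rose) and 14 versus 7 weeks (2610 bp fell, 3157 bp rose) but opposite for 7 versus 5 weeks, where genes that fell had 3144 bp and those that rose 2988 bp. These lengths are the ones implied by the deposited RPKM, and no test of the difference was made.

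A hypothesis set down before its test was that longer transcripts are lower in older livers. The slope of log2 CPM on log2 gene length was computed for each of 20 fish. Its mean was -0.00842 ± 0.0511 at 5 weeks, -0.0195 ± 0.0304 at 7 weeks, 0.00678 ± 0.0417 at 10 weeks and 0.0212 ± 0.0507 at 14 weeks (SD, n = 5). The relation with age had Pearson's r = 0.321 (permutation p = 0.169) and Spearman's rho = 0.302 (permutation p = 0.198), and without any 2 of the 14-week fish, which are all equally far from the median age, r ran from 0.0914 to 0.502 over the 10 pairs. Without 5-week fish 1 and 2 it had r = 0.392 (permutation p = 0.108). In the same family, gene length was also correlated across genes, which are not independent replicates, with each of the 6 changes between ages, and Spearman's rho ran from -0.0196 for 7 versus 5 weeks to 0.0783 for 14 versus 5 weeks. The sign of the relation with age over the 20 fish was opposite to the hypothesis, while rho for 7 versus 5 weeks had the sign of the hypothesis. The test leaves the question open.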
